A study of Mus musculus with 8 samples.

How the data were processed

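Gene expression was measured in single cells of blood and spinal cord from mice with experimental autoimmune encephalomyelitis, at the preclinical, onset, peak and late stage, as 8 libraries. Per the labels, live cells were loaded per library on a 10x Genomics Chromium controller with the chemistry that reads the start of each transcript, with a target of 10000 cells, and libraries were sequenced on an Illumina NovaSeq 6000. The deposited values were raw UMI counts per gene and barcode, made with Cell Ranger 6.1.2 per the file headers and aligned to the mouse genome build mm10 per the submitters' processing notes. Annotation release, cell calling settings and any removal of free RNA or doublets were not given in the sources used here. Each library held exactly 10000 barcodes, and in 5 libraries these reached down to between 18 and 155 UMIs while the other 3 began at 685, 728 and 1399 UMIs. Of 32285 genes in the files, 32235 were matched by gene ID to the GENCODE annotation of mm10, from which coordinates were taken.

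Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 10% of UMIs from mitochondrial genes. This left 8373, 9702, 7187 and 9982 blood barcodes and 6365, 9967, 5731 and 5548 spinal cord barcodes from preclinical to late, with medians of 1934, 1526, 2816 and 2071 UMIs in blood and 3876, 2879, 4168 and 2755 UMIs in spinal cord. Counts were scaled per cell and log-transformed, and 2000 variable genes without antigen receptor genes entered 30 principal components. A shared-neighbour graph on 15 neighbours was clustered by the Leiden method at resolution 1 over all libraries together. Doublets were called per library from the share of simulated doublets among each barcode's neighbours, at a rate of 0.8% per 1000 barcodes, which marked between 246 and 797 barcodes per library. They were removed after clustering. Clusters with 20% or more called doublets were set aside as a whole. That limit was set after the data were examined, and these clusters held 2.93%, 7.45%, 5.44% and 28.3% of blood barcodes and 3.74%, 10.2%, 2.90% and 1.87% of spinal cord barcodes in stage order.

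Clusters received the class of the best of 23 marker sets fixed before the data were examined, when at least 3 markers were 2-fold above the median cluster, the score was at least 0.3 above that of the next class and the 10 leading genes did not point to another class. The class names stand for cells with such markers (T cell-like and so on). The gap did not apply between monocytes and macrophages, which were treated as 1 class. By an override set after the data were examined, a cluster that scored highest for macrophages and next for microglia was named microglia if at least 9 of 10 microglia markers were 2-fold up. Cluster 14, the whole microglia class, was named this way, with a score of 3.49 against 3.91 for macrophages. Clusters with less than 1/3 of their library's median UMIs and mixed leading genes stayed unnamed. Unnamed cells were 0.722%, 0.478%, 1.73% and 9.41% of blood cells and 3.53%, 2.30%, 18.8% and 3.69% of spinal cord cells in stage order. A cluster that came almost entirely from 1 library may stand for that library in place of a cell type.

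Stages were compared within a tissue without a test, since each stage was 1 library. Shares of cells were given with exact Clopper-Pearson 95% intervals, and levels of genes as CPM of the summed UMIs of a class with exact Poisson or conditional binomial 95% intervals of the ratio. These intervals and the floor of 3 counts for undetected genes cover counting error only. A class entered with at least 50 cells in both libraries. For each of 31 gene lists fixed before the data were examined, the median log2 ratio of members with at least 10 counts was placed among 10000 random lists of the same size matched on expression in 20 bins. Members with 0 counts in a library entered at their bound.

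Between tissues, the 4 spinal cord libraries were compared with the 4 blood libraries. Shares were tested by an exact two-sided permutation test with Benjamini-Hochberg adjustment over classes. Genes were tested with edgeR's quasi-likelihood test on UMI counts summed per library and class (TMM scaling, filterByExpr, adjusted p under 0.05), with at least 20 cells per library and class and at least 3 libraries per tissue. Gene lists with at least 5 tested members were tested with camera at a correlation of 0.01, and again with an estimated correlation. Genes were named by a rule fixed before the data were examined. Between tissues, the rule took the 4 genes per direction with the largest fold among called genes with a mean of at least 50 CPM in the higher tissue and no overlap between the tissues. Between stages, it took the 4 largest rises and falls at peak and the 2 largest of late over peak, with a log2 ratio of at least 1 in size, an interval that excluded no difference, and at least 50 CPM and 30 UMIs in the higher library. Immunoglobulin, T cell receptor, ribosomal, mitochondrial and haemoglobin genes, predicted genes (named Gm or Rik), Xist, Y-linked genes and genes 10 times higher in another class were left out of that rule. From the fixed lists, only the 4 members with the largest change per comparison were named, except those marked as chosen later and genes followed over further stages. Some genes that met these rules are not reported here.

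The procedure was tested on simulated data made from the real means and library sizes. Of 200 genes changed 4-fold between tissues, 174 were recovered in T cells, 187 in NK cells, 107 in neutrophils, 176 in monocytes and macrophages and 173 in conventional dendritic cells, with 10, 12, 9, 16 and 3 false calls. In simulated peak over preclinical ratios of spinal cord T cells, 96.0% of the 95% intervals held the true value. There both libraries were drawn as Poisson counts from a shared profile, apart from the changed genes. Such coverage follows from that design and does not test the spread between animals or libraries. The alternatives tried were other limits on UMIs (300, 1000 and 1400) and mitochondrial UMIs (5%), doublets kept, resolutions 0.5 and 2, other denominators for shares, DESeq2 and its size factors, no filter on low counts, stage as a replicate block, and each library left out in turn. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.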

Results

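Immune cells of blood and spinal cord were profiled by single-cell RNA sequencing at 4 stages of experimental autoimmune encephalomyelitis, a mouse model of multiple sclerosis in which T cells attack the central nervous system. The disease was induced by transfer of Th17 cells, the T helper cells that make interleukin-17. Each tissue contributed 1 library at the preclinical, onset, peak and late stage, 8 libraries in all, and each library held 10000 barcodes. The 4 blood libraries held 20664882, 23214909, 28037393 and 24432187 unique molecular identifiers (UMIs) from preclinical to late, and the 4 spinal cord libraries 29901451, 33033651, 27993798 and 21562826. After quality filters and removal of doublets, 7761, 8788, 6712 and 6918 blood cells and 6000, 8614, 5433 and 5251 spinal cord cells were analysed, again from preclinical to late. The labels do not say how many animals each library came from. Stages were therefore compared as values, with 95% intervals that cover counting error only and with no replicate check. Between tissues the 4 stages of each tissue served as its replicates, so p-values measure the spread between these libraries. That spread includes the change between stages and may also be technical.

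The first comparison asked how the cell types of each tissue changed in proportion over the disease. In the spinal cord, T cells were 4.05% of cells at the preclinical stage, 3.08% at onset, 11.6% at peak and 20.5% at the late stage, a late minus preclinical difference of 16.4 ± 1.21 percentage points (95% counting interval). Monocytes and macrophages, the phagocytes that enter from blood, went the other way, from 36.0% at the preclinical stage through 48.2% at onset to 29.2% at peak and 9.06% at the late stage. Microglia, the resident phagocytes of the central nervous system, were 1.78%, 2.69%, 4.97% and 10.9% of spinal cord cells in stage order. Neutrophils remained a large class in the spinal cord at every stage, with 41.6%, 29.6%, 24.8% and 37.6%. Stem or progenitor cells, marked by granule genes such as Elane and Mpo, were 0.883%, 0.627% and 0.902% at the first 3 stages and 6.0% at the late stage. Conventional dendritic cells, which present antigen to T cells, were 5.08% of spinal cord cells at the preclinical stage and 1.43% at the late stage, and migratory dendritic cells were 3.88% and 0.114%. Of the 3.88%, 2.42% lay in cluster 33, seen in that library only and led by Ccl2, Cxcl10 and Isg15, and the other cluster of the class was 1.47%, 2.25%, 1.53% and 0.114% of cells in stage order. B cells were 0.100% of spinal cord cells at the preclinical stage and 3.03% at the late stage.

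In blood, neutrophils were 68.1%, 59.5% and 42.2% of cells at the preclinical, onset and peak stages but 0.289% (Clopper-Pearson 95% interval 0.177 to 0.446%, 20 cells) at the late stage. B cells were 1.49% of blood cells at the preclinical stage and 23.3% at the late stage, a difference of 21.8 ± 1.04 points, which was 5.84 points with at most 5% mitochondrial UMIs. Monocytes were 6.35% and 38.7%, conventional dendritic cells 0.258% and 7.81%, and plasmacytoid dendritic cells, a main source of type I interferon, 0.0129% and 4.24%. Natural killer (NK) cells, the innate lymphocytes that kill stressed or infected cells, were 21.1%, 18.7%, 24.7% and 12.3% of blood cells in stage order. T cells were 1.64%, 1.88%, 3.72% and 2.72%, and as a share of cells other than neutrophils their late minus preclinical difference was -2.40 points. The late blood library had no barcode under 1399 UMIs, while the preclinical, onset and peak blood libraries reached down to 155, 728 and 18 UMIs, and such a floor can set the share of neutrophils, which hold little RNA, and with it the share of each other blood class. In the same library 28.3% of barcodes lay in clusters rich in doublets and were left out, against 2.93%, 7.45% and 5.44% at the earlier stages. Cluster 13 among them scored highest for NK cells and held 16, 102, 83 and 1143 blood barcodes in stage order. Cluster 20 did so too and held 167, 190, 114 and 182. The late NK share therefore depends on leaving them out. At least 4 of 8 NK cell markers were seen in 1690, 1947, 1950 and 2410 kept blood barcodes in stage order, doublets included. These are out of 8373, 9702, 7187 and 9982 kept barcodes.

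**Figure D1:**
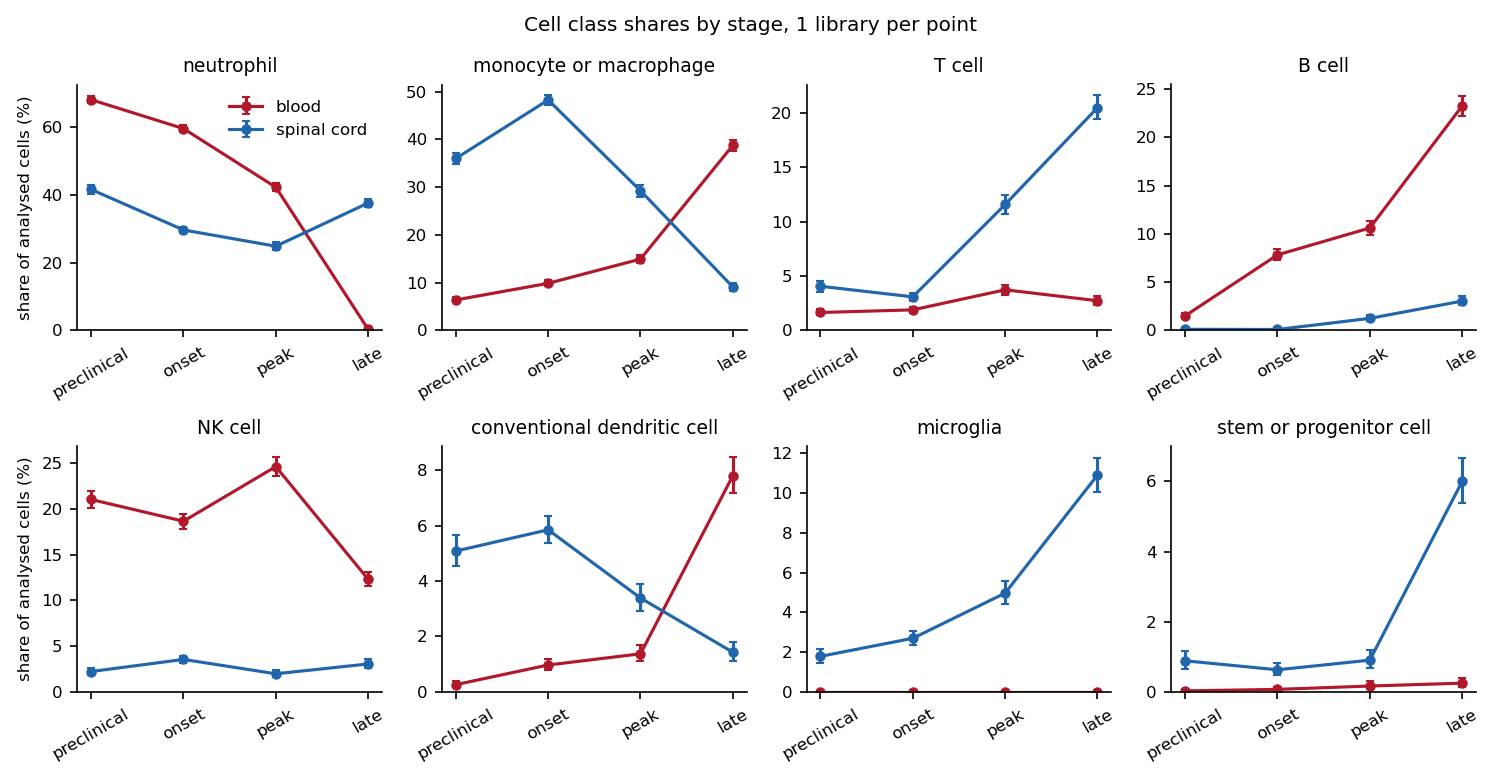
Share of analysed cells (%) of the main cell classes by disease stage, in blood (red) and spinal cord (blue), where each point is 1 library and the bar its 95% Clopper-Pearson interval. The spinal cord T cell share went from 4.05% to 20.5% between the preclinical and the late stage, and the blood neutrophil share from 68.1% to 0.289%.

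The next comparison asked how gene expression within each spinal cord cell class changed between stages. In spinal cord T cells (243, 265, 629 and 1076 cells in stage order) cytokine genes of the Th17 cell were highest early and lowest late. Il17a, which encodes interleukin-17A, was at 511, 678, 257 and 49.7 CPM (UMIs of a gene scaled to the total UMIs of the class in the library) at the preclinical, onset, peak and late stages. Il17f was at 116 CPM at the preclinical stage and 2.14 CPM at peak, a log2 ratio of -5.77 (counting interval -7.11 to -4.69). Il22, an interleukin that acts on epithelia, was at 252 CPM at the preclinical stage and not detected at peak (0 of 3276176 UMIs), a log2 ratio of at most -8.10 against a floor of 3 counts in that library. Csf2, which encodes the myeloid growth factor GM-CSF, was at 382 CPM at the preclinical stage and 17.1 CPM at the late stage. Ifng, the gene of interferon-gamma, was at 935, 1114, 223 and 185 CPM in stage order. Among 14 measured genes of the Th17 programme, none was higher at the late stage than at peak, and the median log2 ratio of -1.63 lay at percentile 0 of 10000 random lists matched on expression.

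Genes of regulatory T cells, which restrain other T cells, were higher at peak than at the preclinical stage. The median log2 ratio of the regulatory list was 1.11 (percentile 100, 6 of 9 measured members higher, with a gene at 0 counts set to its bound). Ikzf2, a transcription factor of these cells, was at 44.9 CPM at the preclinical stage and 486 CPM at peak. Il10, an anti-inflammatory cytokine, was at 3.21 and 37.2 CPM. Foxp3, the defining factor of regulatory T cells, was not detected at the preclinical stage (0 of 1247379 UMIs, which allows up to 2.41 CPM) and was at 34.8 CPM at peak, a log2 ratio of at least 3.85. All 10 measured genes of the checkpoint list were higher at peak than at the preclinical stage (median log2 ratio 0.94, percentile 100). The list holds receptors that dampen T cell activation, such as Lag3 and Pdcd1, and others, such as Tox and the costimulatory receptor Tnfrsf9. Tox, a factor of chronically stimulated T cells, was at 48.9, 416 and 1470 CPM at the preclinical, peak and late stages. Lag3 was at 41.7, 139 and 45.8 CPM, and Pdcd1, which encodes the receptor PD-1, at 80.2, 208 and 204 CPM. At the late stage, Il2ra and Tnfrsf4 were lower than at peak (log2 ratio -1.62, interval -1.77 to -1.47, and -2.24, interval -2.47 to -2.01), and Ccl5 and Gzmk, expressed by cytotoxic T cells, were higher (1.78, interval 1.75 to 1.82, and 1.34, interval 1.17 to 1.52). Nrgn (10.4 to 625 CPM) and Izumo1r (3.21 to 59.5 CPM), which encodes the folate receptor FR4, were higher at peak than at the preclinical stage, and Batf3 (75.4 to 8.55 CPM) was lower. Lta, the gene of lymphotoxin alpha, was at 75.7 CPM at peak and 6.50 CPM at the late stage.

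T cells came from different clusters at different stages. Cluster 15, with Il17a and Il2ra among its leading genes, held 213, 187, 416 and 244 spinal cord barcodes in stage order, and cluster 10, with Cd8b1 and Gzmk among its leading genes, held 28, 69, 192 and 836. Cluster 36, with Ikzf2, Cd160, Xcl1 and the gamma-delta T cell marker Trdc among its leading genes and NK cells as its second class, held 4, 10, 36 and 41. The rise of Ikzf2 can therefore not be assigned to regulatory T cells alone. Within cluster 15 alone, Il17a was at 600, 913, 379 and 228 CPM. Genes of other cell types were also measured in these T cells. The MHC class II list, whose genes are carried by antigen-presenting cells, had a median log2 ratio of 1.94 from the preclinical stage to peak, the early granule list of neutrophil precursors 2.83, and the complement list 0.93.

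**Figure D2:**
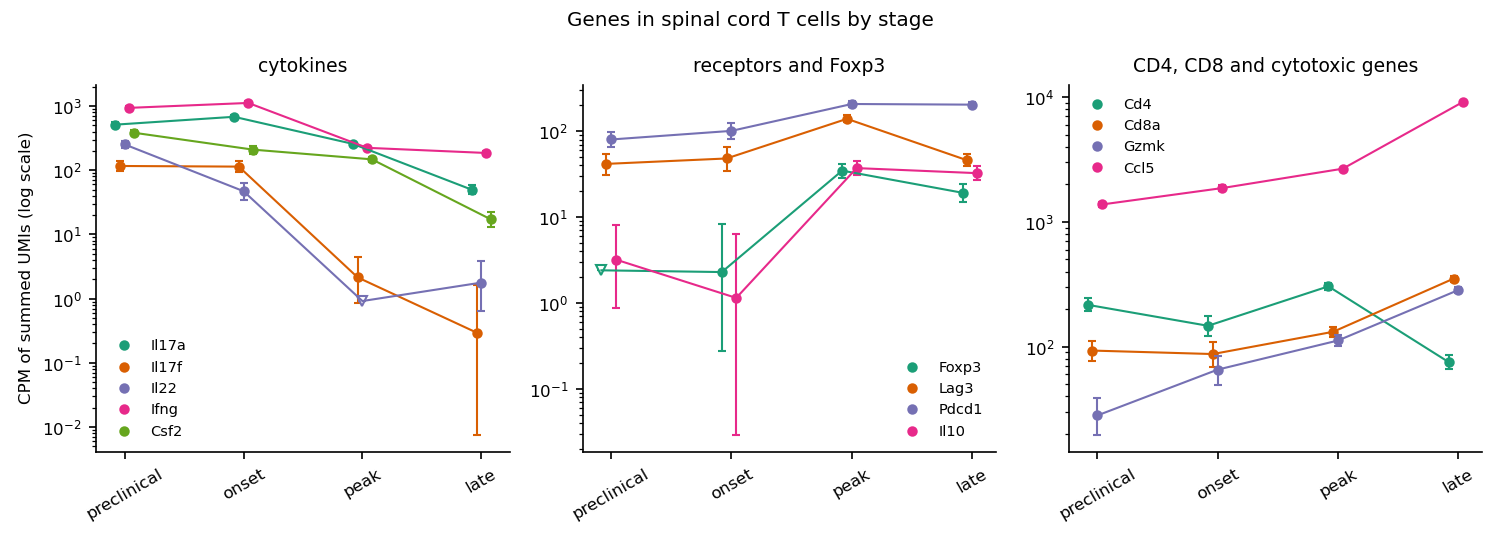
Expression in spinal cord T cells (CPM, log axis) by disease stage of cytokine, regulatory, checkpoint and subset genes, of which Foxp3, Lag3, Pdcd1, Cd4 and Cd8a were chosen for display after their values were seen. Points are single libraries with 95% exact Poisson intervals and open triangles mark the floor of 3 counts where no UMI was seen. Il17a went from 511 to 49.7 CPM and Cd8a from 93.0 to 351 CPM between the preclinical and the late stage.

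Spinal cord monocytes and macrophages (2159, 4156, 1588 and 476 cells) showed interferon genes lower at peak and lipid handling genes higher. All 15 measured interferon-stimulated genes were lower at peak than at the preclinical stage, with a median log2 ratio of -2.52 (percentile 0). Slfn4 went from 359 to 30.2 CPM and Oasl1, an antiviral gene, from 312 to 26.5 CPM. The interferon-gamma response list had a median of -1.40 (percentile 0, 1 of 16 members higher) and the chemokine list one of -0.83 (percentile 0, 3 of 17 higher). The chemokine gene Cxcl10, which attracts T cells, was at 2705 CPM at the preclinical stage and 459 CPM at peak, and Ccl2, which attracts monocytes, at 1056 and 190 CPM. In the list of lipid-associated and disease-associated phagocytes, 13 of 17 members were higher at peak (median 0.83, percentile 100). Gpnmb, a glycoprotein of lipid-laden macrophages, went from 29.2 to 441 CPM (log2 ratio 3.92, interval 3.77 to 4.07), and Apoe, which encodes a lipid carrier, from 3287 to 18386 CPM. The antigen presentation genes H2-Aa and H2-Eb1 went from 1396 to 2882 CPM and from 1074 to 2319 CPM. Over all genes the median log2 ratio between these stages was 0.27, against which the ratios should be read. The cells moved between clusters: cluster 2, with Cxcl10 and Ccl2 among its leading genes, held 1607 at the preclinical stage and 500 at peak, and cluster 7, with Gpnmb among them, 429 and 963. Within clusters 2 and 7 the interferon-stimulated medians were -2.08 and -2.31 in the spinal cord (both percentile 0), and those of the phagocyte list 0.30 and 0.52 (percentiles 95.9 and 99.1).

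From peak to the late stage, the same class had lower levels of genes of arginine and nitric oxide metabolism, hypoxia and glycolysis. None of 8 nitric oxide and arginine genes was higher at the late stage (median -3.15, percentile 0). Arg1, the gene of arginase 1, went from 1509 to 5.15 CPM (log2 ratio -8.20, interval -9.15 to -7.39). Nos2, which makes nitric oxide, was at 405 CPM at the preclinical stage, 67.4 CPM at peak and not detected at the late stage (0 of 2331081 UMIs, a log2 ratio of at most -5.71). Of 14 glycolysis genes 1 was higher (median -1.42, percentile 0), and Ldha, which encodes lactate dehydrogenase, went from 655 to 183 CPM. Of 8 hypoxia genes 1 was higher (median -2.10, percentile 0), and Vegfa, a growth factor for vessels, went from 206 to 45.5 CPM. Proliferation genes were higher in 13 of 14 cases (median 2.57, percentile 100). Most cells of this class lay in clusters 2 and 7 up to peak and in cluster 22 at the late stage. Clusters 2 and 7 held 513 and 997 spinal cord barcodes at peak and 10 and 87 at the late stage. Cluster 22, with F13a1, Vcan and Ccr2 among its leading genes, held 93 and 310. The ratios from peak to late therefore compare different clusters. RNA of red cells was higher too: the median of 5 haemoglobin and other erythroid genes was 10.12, and Hba-a1 went from 0.185 to 416 CPM (2 UMIs at peak, log2 ratio 11.14, interval 9.28 to 14.18). Early granule genes of neutrophil precursors had a median of 2.80 (11 of 12 higher).

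Spinal cord microglia (107, 232, 270 and 573 cells) had antigen presentation and disease-associated genes higher at peak and late than at the preclinical stage, and cell cycle genes lower. The MHC class II list had a median log2 ratio of 2.25 at peak (percentile 100, 8 of 9 higher). H2-Aa was at 170, 1636 and 1119 CPM at the preclinical, peak and late stages and Cd74, the invariant chain, at 539, 5253 and 3457 CPM. Of 17 disease-associated genes 15 were higher at peak (median 1.55, percentile 100) and 16 at the late stage (median 2.17). Apoe was at 981, 15669 and 55805 CPM, and Igf1, an insulin-like growth factor, at 1.15, 65.2 and 170 CPM (1 UMI at the preclinical stage, log2 ratio at peak 5.82, interval 3.32 to 11.14). Lpl, the gene of lipoprotein lipase, went from 55.8 CPM at peak to 536 CPM at the late stage, and Spp1, which encodes osteopontin, from 336 to 1732 CPM. The acute phase gene Saa3 went from 2.31 CPM at the preclinical stage to 454 CPM at peak (2 UMIs at the preclinical stage, log2 ratio 7.62, interval 5.76 to 10.67). All 14 proliferation genes were lower at peak than at the preclinical stage (median -1.38, percentile 0), among them Pclaf, a replication factor (79.6 to 15.4 CPM). Hmgcs1 (76.1 to 11.5 CPM) and Fdps (50.8 to 7.47 CPM), which encode enzymes of cholesterol synthesis, were lower as well. Of 14 homeostatic microglia genes 4 were higher at peak (median -0.46, percentile 0.26), and P2ry12, a purine receptor that marks resting microglia, was at 553, 423, 396 and 403 CPM in stage order.

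Spinal cord neutrophils (2494, 2551, 1348 and 1973 cells) had lower interferon genes at peak than at the preclinical stage, and lower chemokine and higher granule genes at the late stage than at peak. None of 14 interferon-stimulated genes was higher at peak than at the preclinical stage (median -2.37, percentile 0), and Ifit3 went from 450 to 35.9 CPM. From peak to the late stage none of 13 chemokine genes was higher (median -4.10, percentile 0), and Ccl3 went from 850 to 21.2 CPM. The guanylate-binding protein gene Gbp5 went from 267 to 1.10 CPM and the interleukin-1 alpha gene Il1a from 290 to 4.69 CPM. All 12 early granule genes were higher at the late stage than at peak (median 1.54, percentile 100), and Camp, which encodes the antimicrobial peptide cathelicidin, was at 3996, 7891 and 24031 CPM at the preclinical, peak and late stages. Cluster 3 held 2239, 2376, 652 and 0 of these cells in stage order, cluster 6 held 187, 154, 579 and 1485 and cluster 19 held 50, 9, 100 and 410, so the stages compare different clusters. From the preclinical stage to peak, the interferon-stimulated median was -1.97 (percentile 0) within cluster 3 and 0.26 (percentile 58.9) within cluster 6 of the spinal cord. From peak to the late stage, the chemokine median was -1.59 within cluster 6 and 0.78 within cluster 19, and the early granule median 0.86 and 0.39. The median over all genes was 0.38 for peak over preclinical and -0.33 for late over peak. RNA of myelin genes in this class had a median log2 ratio of 2.34 from the preclinical stage to peak.

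Spinal cord conventional dendritic cells (305, 504, 184 and 75 cells) had lower interferon genes at peak than at the preclinical stage. None of 15 interferon-stimulated genes was higher at peak (median -2.11, percentile 0), with Oasl1 at 199 and 24.4 CPM and Iigp1, an interferon-induced GTPase, at 531 and 73.3 CPM. From peak to the late stage Ccl17, a chemokine gene for T cells, went from 685 to 16.4 CPM, and Ifitm1 from 1919 to 47.0 CPM.

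**Figure D3:**
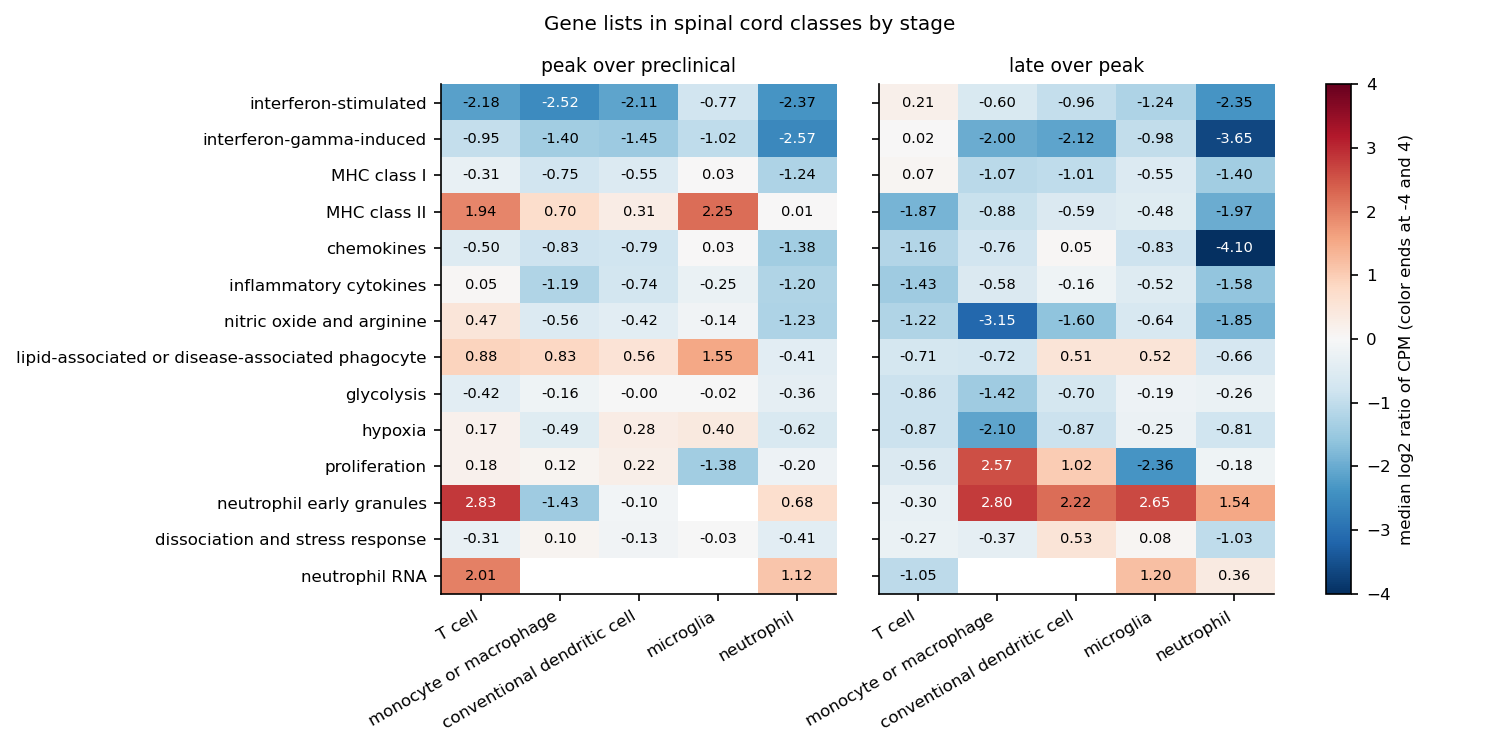
Heat map of the median log2 ratio of 14 gene lists in 5 spinal cord cell classes, for peak over preclinical and late over peak, with the colour scale ending at -4 and 4 and blank fields where fewer than 5 members were measured. Interferon-stimulated genes were lower at peak in monocytes and macrophages (median -2.52), neutrophils (-2.37), T cells (-2.18) and conventional dendritic cells (-2.11).

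Blood cell classes were compared between stages in the same way. Blood neutrophils (5283, 5232 and 2834 cells up to peak) had granule genes higher at peak than at the preclinical stage. Of 9 early granule genes 7 were higher (median 3.11, percentile 100). Ltf, which encodes lactoferrin, went from 101 to 1767 CPM, Camp from 246 to 3876 CPM and Ngp from 356 to 5053 CPM. Igfbp6 went from 512 to 12.6 CPM and Wfdc17 from 10384 to 623 CPM. Clusters 0 and 16 held most blood neutrophils at the preclinical stage, cluster 16 being almost entirely from that library, and cluster 8 at peak. In blood NK cells (1634, 1641, 1655 and 852 cells), Bcl2, a survival gene, went from 825 to 1721 CPM between the preclinical stage and peak, and the chemokine genes Xcl1 and Ccl4 from 343 to 132 CPM and from 1075 to 440 CPM. In blood T cells (127, 165, 250 and 188 cells), Gzmk went from 27.8 to 290 CPM from the preclinical stage to peak, while cluster 10, which Gzmk helps to define, went from 67 to 211 of these cells and cluster 15 from 47 to 27. Within cluster 10, Gzmk went from 44.8 to 334 CPM. In the same class, all 14 proliferation genes were higher at the late stage than at peak (median 1.09, percentile 100), with Mki67 at 222 and 563 CPM. Early granule genes of neutrophil precursors had a median of 5.89 in the same T cells. In blood B cells (116, 687, 712 and 1609 cells), S100a4 went from 200 to 989 CPM and Vpreb3, a gene of immature B cells, from 86.2 to 15.3 CPM between the preclinical stage and peak, and none of 13 interferon-stimulated genes was higher at the late stage than at peak (median -0.95, percentile 0).

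Blood monocytes (493, 864, 1001 and 2680 cells) had 13 of 15 interferon-stimulated genes higher at peak than at the preclinical stage (median log2 ratio 0.51, percentile 100). Flt3, a growth factor receptor of dendritic cell precursors, went from 19.0 to 119 CPM and Cd274, which encodes PD-L1, from 81.4 to 19.8 CPM. The mix of clusters moved, with 175 cells in cluster 4 and 317 in cluster 12 at the preclinical stage against 568 and 425 at peak. Within clusters 4 and 12 of blood, the interferon-stimulated medians were 0.32 and 0.19, the log2 ratios of Flt3 2.19 and 4.00, and those of Cd274 -0.284 (interval -1.42 to 0.994) and -1.93. From peak to the late stage, Fkbp5 and Ddit4, both known to be induced by glucocorticoid hormones, went from 1133 to 64.2 CPM and from 157 to 14.4 CPM. Blood conventional dendritic cells had the same 2 genes at 1018 and 76.8 CPM and at 227 and 16.1 CPM. Fkbp5 was higher at peak than at the preclinical stage in each of 12 tissue and class pairs with enough cells, and lower at the late stage than at peak in each of 13.

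**Figure D4:**
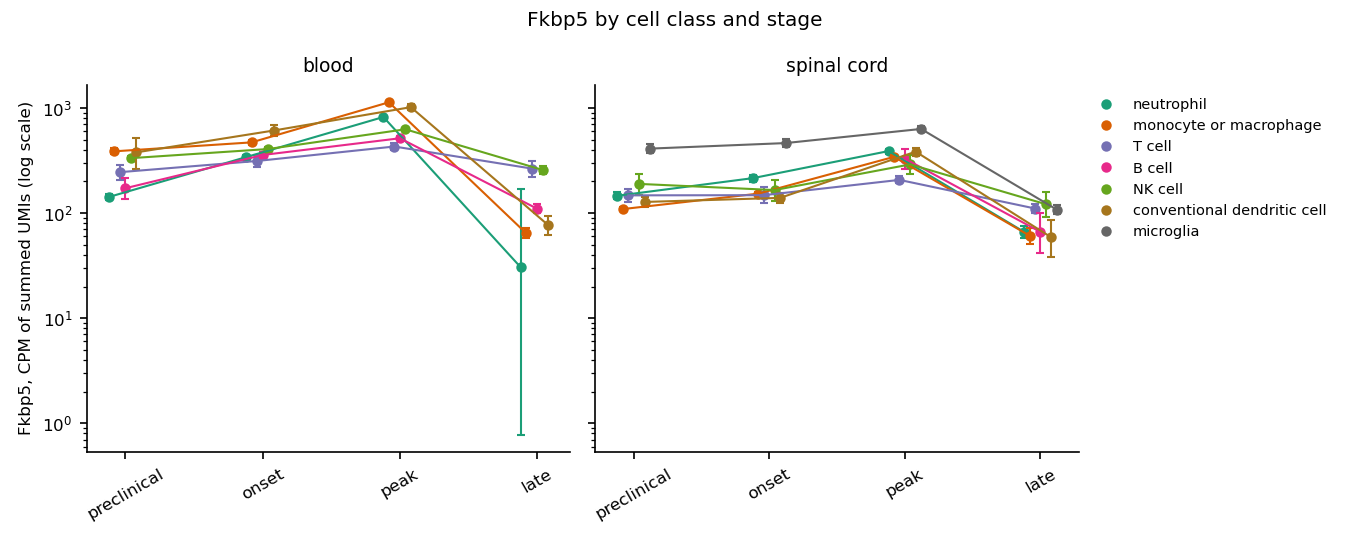
Fkbp5 expression (CPM, log axis) by disease stage in cell classes of blood and spinal cord, each point 1 library with its 95% exact Poisson interval. In blood monocytes Fkbp5 was at 387, 1133 and 64.2 CPM at the preclinical, peak and late stages, and in spinal cord microglia at 411, 632 and 108 CPM.

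The last comparisons set spinal cord against blood, first for cell proportions. NK cells were 2.69 ± 0.729% of spinal cord cells and 19.2 ± 5.19% of blood cells (mean ± SD, n = 4 libraries each). Microglia were 5.09 ± 4.11% of spinal cord cells and were not seen in blood. T cells were 9.80 ± 8.08% and 2.49 ± 0.945%, migratory dendritic cells 1.94 ± 1.57% and 0.0877 ± 0.0829%, and B cells 1.11 ± 1.39% and 10.8 ± 9.14%, in spinal cord and blood respectively. None of 13 classes passed an exact two-sided permutation test after Benjamini-Hochberg adjustment. The NK cell, microglia, oligodendrocyte and progenitor shares did not overlap between tissues and had an exact permutation p = 0.0286, the smallest that 4 against 4 libraries allow, with adjusted p = 0.0929. Neutrophils (33.4 ± 7.58% and 42.5 ± 30.1%, exact permutation p = 0.571) and monocytes and macrophages (30.6 ± 16.4% and 17.5 ± 14.6%, exact permutation p = 0.343) overlapped between the tissues. Without the late blood library, neutrophils were 56.6 ± 13.2% of blood cells and did not overlap with spinal cord (exact permutation p = 0.0286, adjusted p = 0.106).

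Genes of each class were then tested between tissues with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. In T cells, 466 genes were higher in spinal cord and 304 in blood among 8565 tested. Il17a (ENSMUSG00000025929, mm10 chromosome 1, 20730905 to 20734496, plus strand) was at 374 ± 277 CPM in spinal cord and was not detected in blood, at least 257-fold higher against a floor of 3 counts over the summed blood UMIs (adjusted p = 0.00276). Ccl1 (ENSMUSG00000020702, chromosome 11, 82176657 to 82305690, minus strand), a chemokine gene, was at 319 ± 250 CPM and undetected in blood, at least 330-fold higher (adjusted p = 0.00280). Areg, which encodes the growth factor amphiregulin, was at 51.6 ± 46.1 CPM and undetected in blood (at least 62.6-fold, adjusted p = 0.00688). Csf2 (ENSMUSG00000018916, chromosome 11, 54247271 to 54249667, minus strand) was at 189 ± 152 CPM against 0.382 ± 0.764 CPM, a 414-fold ratio of summed counts (interval 74.2 to 16370, 1 UMI in blood). Ncr1 and Klrb1c, which encode NK cell receptors, were higher in blood T cells and 3.22 and 3.69 times higher still in NK cells. Ncr1 (ENSMUSG00000062524, chromosome 7, 4337724 to 4345164, plus strand) was at 155 ± 102 CPM in blood and 5.26 ± 5.96 CPM in spinal cord (log2 fold change -4.34 ± 0.618 SE, adjusted p = 0.00142), and Klrb1c was at 125 ± 68.3 and 9.04 ± 6.06 CPM (adjusted p = 0.000942).

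Among the gene lists in T cells, 8 of 11 tested Th17 genes rose in spinal cord and none fell (10 adjusted over the list alone, camera adjusted p = 1.7e-10, adjusted p = 0.0776 with an estimated correlation). Of 10 checkpoint genes 7 rose (7 up and 1 down adjusted over the list alone, camera adjusted p = 4.69e-10, adjusted p = 0.0379 with an estimated correlation), such as Tnfrsf9, a costimulatory receptor (log2 fold change 4.04), Pdcd1 (3.20) and Ctla4 (3.17). Regulatory genes rose in 5 of 6 cases (5 adjusted over the list alone, camera adjusted p = 2.55e-07), with Tnfrsf4 at 4.46 and Il2ra at 4.23. Only these 6 of the 10 listed genes were tested. Il2ra and Ctla4, both on this list, were among the leading genes of cluster 15 beside Il17a and Ifng. The rise of this list can therefore not be assigned to regulatory T cells alone. Genes of naive and recirculating lymphocytes fell in 5 of 9 cases (6 adjusted over the list alone, camera adjusted p = 7.67e-10), among them Klf2 (-2.70) and Klf3 (-2.88). Of 9 NF-kB genes 7 rose (9 adjusted over the list alone, camera adjusted p = 7.61e-15), with Tnfaip3 at 2.53. Of 15 genes of the dissociation and stress response, which tissue handling can induce, 11 rose (14 adjusted over the list alone, camera adjusted p = 5.64e-18), with Nr4a1 at 4.35 and the heat shock gene Hspa1b at 3.76. Clusters 10, 15 and 36 of this class were unequally divided between the tissues, with blood T cells of the peak and late stages mostly in cluster 10. Without one library the count of changed genes was 495 (blood onset), 487 (blood peak), 500 (spinal cord preclinical), 465 (spinal cord peak) or 1256 (spinal cord late). In cluster 15 alone Il17a had a log2 fold change of 11.63 (adjusted p = 0.00108), and in cluster 10 alone Ncr1 had one of -4.82 (adjusted p = 0.000267).

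In NK cells, 586 genes were higher in spinal cord and 271 in blood among 8418 tested by edgeR. Emb, an adhesion molecule, was at 904 ± 162 CPM in spinal cord and 71.6 ± 19.1 CPM in blood (log2 fold change 3.78 ± 0.216, adjusted p = 6.88e-09), and Pmepa1, a target of TGF-beta signalling, at 196 ± 88.2 and 2.24 CPM (adjusted p = 3.27e-08). S1pr5 (ENSMUSG00000045087, chromosome 9, 21242912 to 21248443, minus strand), the receptor for exit into blood, fell, with 23.3 ± 13.5 CPM in spinal cord and 132 ± 15.7 CPM in blood (-2.42 ± 0.291, adjusted p = 2.48e-05), as did Cx3cr1 (-2.48), Klrg1 (-1.93) and Zeb2 (-1.74). Of 12 dissociation and stress genes 8 rose (10 adjusted over the list alone, camera adjusted p = 1.88e-13, adjusted p = 0.0272 with an estimated correlation), with Nr4a1 at 3.01 and Jun at 2.69. Of 5 hypoxia genes 4 rose (4 adjusted over the list alone, camera adjusted p = 1.5e-05), led by Vegfa at 3.31. Of 7 interferon-stimulated genes 4 rose (6 adjusted over the list alone, camera adjusted p = 0.000143, adjusted p = 0.296 with an estimated correlation). Haemoglobin RNA was lower in spinal cord NK cells (Hbb-bt -12.14) and RNA of phagocytes higher (C1qa 5.58). The count of changed genes was 537 without peak blood, 528 without preclinical spinal cord and 497 without onset spinal cord.

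In monocytes and macrophages, 1544 genes were higher in spinal cord and 1225 in blood among 10826 tested by edgeR. Vegfa (ENSMUSG00000023951, chromosome 17, 46016993 to 46032369, minus strand) was at 187 ± 97.7 CPM in spinal cord and undetected in blood, at least 1266-fold higher (adjusted p = 0.00129). Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484, minus strand) was at 1329 ± 903 CPM against 0.209 CPM (log2 fold change 12.69 ± 1.86, adjusted p = 0.00185), and Inhba, an activin subunit, at 494 ± 408 CPM, a 5460-fold ratio of summed counts (interval 1511 to 45084, 2 UMIs in blood). Ace (ENSMUSG00000020681, chromosome 11, 105967945 to 105989964, plus strand), a gene of patrolling monocytes, was at 8.01 ± 9.30 CPM in spinal cord and 226 ± 103 CPM in blood (-4.86 ± 0.703, adjusted p = 0.00175), and Cd300e (-6.41) and Tgfbr3 (-5.83) fell as well. Of 16 chemokine genes 14 rose (14 adjusted over the list alone, camera adjusted p = 1.94e-16, adjusted p = 0.108 with an estimated correlation), among them Cxcl3 (10.62) and Ccl12 (8.65). Of 16 disease-associated genes 14 rose (14 adjusted over the list alone, camera adjusted p = 1.32e-11, adjusted p = 0.0952 with an estimated correlation), with Spp1 at 9.85 and Gpnmb at 7.49. All 8 hypoxia genes and 13 of 14 glycolysis genes rose (8 and 13 adjusted over the list alone, camera adjusted p = 1.09e-05 and adjusted p = 1.78e-07, adjusted p = 0.249 and adjusted p = 0.289 with an estimated correlation), as did 6 of 7 nitric oxide and arginine genes (6 adjusted over the list alone, camera adjusted p = 2.52e-05, adjusted p = 0.249 with an estimated correlation). Of 12 complement genes 8 rose (9 up and 1 down adjusted over the list alone, camera adjusted p = 5.42e-10, adjusted p = 0.0952 with an estimated correlation), led by C1qa at 6.69. Blood cells of this class lay in clusters 4 and 12 and spinal cord cells in clusters 2, 7 and 22. The count was 1700 without peak blood, 1611 without preclinical, 1616 without onset and 4224 without late spinal cord.

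In neutrophils, 470 genes were higher in spinal cord and 233 in blood among 8857 tested by edgeR. Il1a (ENSMUSG00000027399, chromosome 2, 129299610 to 129309972, minus strand) was at 555 ± 485 CPM in spinal cord and 0.313 ± 0.417 CPM in blood, a 1464-fold ratio of summed counts (interval 743 to 3393, adjusted p = 0.0140). The chemokine gene Ccl3 was at 1443 ± 1227 and 5.49 ± 3.87 CPM (adjusted p = 0.0144), and Hilpda, a lipid droplet gene induced by hypoxia, at 86.4 ± 60.8 and 0.993 CPM (adjusted p = 0.00589). Slc44a2, a choline transporter, fell (-2.21, adjusted p = 0.0129). The calls of Il1a, Ccl3 and Slc44a2 were lost without the preclinical or the onset blood library, and those of Il1a and Ccl3 also without peak blood. Of 16 dissociation and stress genes 1 rose (4 adjusted over the list alone, camera adjusted p = 0.000166, adjusted p = 0.360 with an estimated correlation). Of 10 NF-kB genes 6 rose (9 adjusted over the list alone, camera adjusted p = 4.54e-07, adjusted p = 0.303 with an estimated correlation), with Icam1 at 6.22 and Cd83 at 5.14, and of 8 inflammatory cytokine genes 4 rose (4 adjusted over the list alone, camera adjusted p = 0.000264, adjusted p = 0.312 with an estimated correlation), with Tnf at 5.50. RNA of phagocytes was higher in spinal cord neutrophils too (C1qa 5.16). The count of changed genes rested on single libraries: it was 19 without the preclinical blood library, 20 without onset blood, 130 without peak blood, and 240, 349, 450 and 2589 without the preclinical, onset, peak and late spinal cord library. The late blood library entered with 20 neutrophils, the minimum, and without it the count was 1440. Of these 20, 19 lay in cluster 19, led by the early granule genes Ltf, Ngp and Camp, and 1 in cluster 8. Cluster 0, which held most neutrophils of preclinical and onset blood, had none. The late blood profile therefore comes from other neutrophil clusters than those of earlier blood.

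In conventional dendritic cells, 809 genes were higher in spinal cord and 577 in blood among 8254 tested by edgeR. Ccl22 (ENSMUSG00000031779, chromosome 8, 94745590 to 94751699, plus strand), a chemokine gene for T cells, was at 171 ± 105 CPM in spinal cord and undetected in blood, at least 184-fold higher (adjusted p = 0.000635). Nr4a3, an immediate early gene, was at 587 ± 99.5 CPM, a 1506-fold ratio of summed counts (interval 270 to 59492, 1 UMI in blood, adjusted p = 1.79e-07). Cxcl10 was at 745 ± 669 and 3.31 CPM (adjusted p = 0.00158), and Ptgs2, which makes prostaglandins, at 113 ± 40.5 CPM, a 128-fold ratio (interval 35.3 to 1061, 2 UMIs in blood). Ccl22, a marker of migratory dendritic cells, was 3.74 times higher still in that class, in the spinal cord library where it was highest. By the same measure Ptgs2 was 4.06 times higher in basophils or mast cells and Cxcl10 2.38 times higher in neutrophils. Whether such cells or their RNA contributed was not tested. Rfx2 was at 3.81 ± 1.19 CPM in spinal cord and 111 ± 34.9 CPM in blood (-4.52 ± 0.342, adjusted p = 9.53e-06). Of 11 chemokine genes 9 rose and 1 fell (9 and 2 adjusted over the list alone, camera adjusted p = 1.59e-15, adjusted p = 0.0124 with an estimated correlation), with Ccl4 at 7.35, and of 7 inflammatory cytokine genes 5 rose (5 adjusted over the list alone, camera adjusted p = 6.33e-09, adjusted p = 0.0124 with an estimated correlation), with Il6 at 7.01 and Il1b at 4.78. Interferon-stimulated genes rose in 13 of 15 cases (14 adjusted over the list alone, camera adjusted p = 2.13e-06, adjusted p = 0.302 with an estimated correlation), with Isg15 at 3.94, and MHC class I genes rose in 8 of 9 (9 adjusted over the list alone, camera adjusted p = 5.14e-05, adjusted p = 0.279 with an estimated correlation). Dissociation and stress genes, which tissue handling can induce, also rose in this class, as given under Other observations. The count of changed genes was 673 without late blood, 669 without preclinical, 684 without onset and 2462 without late spinal cord.

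**Figure D5:**
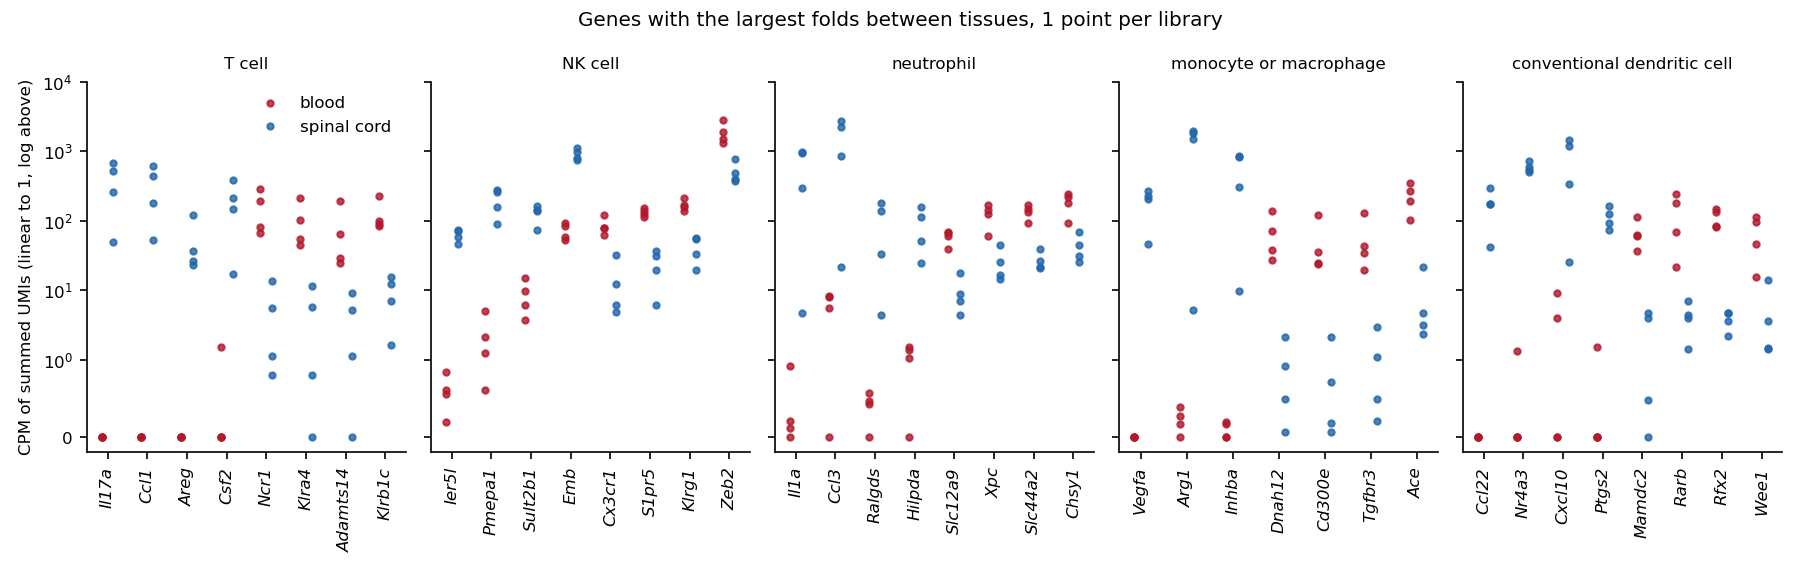
CPM per library of named genes of 5 cell classes in blood and spinal cord, on an axis that is linear to 1 and logarithmic above it. Il17a in T cells averaged 374 CPM in spinal cord with no UMI in blood, and Ace in monocytes and macrophages 8.01 CPM in spinal cord and 226 CPM in blood.

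B cells were not tested between tissues, since fewer than 3 spinal cord libraries held 20 of them. Genes that were at least 10 times higher in another class of the same library made up 29 of the 770 called genes in T cells, 51 of 857 in NK cells, 51 of 703 in neutrophils, 102 of 2769 in monocytes and macrophages and 47 of 1386 in conventional dendritic cells. The libraries of the tissues did not overlap for 1460, 1525, 1112, 3139 and 1565 of the tested genes in the same order, where chance gives 2.86%.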

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

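The tests that weigh the 3 patterns below were chosen after the results were seen. Of 26 groups of 4 shares tested for a library far from the others 7 had one, and of 106 groups including named genes 15 did, where chance marks about 1 in 20.

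Neutrophils made up 0.289% of late blood cells against 42.2 to 68.1% at the earlier stages. Of the late blood neutrophils, 19 lay in cluster 19 and 1 in cluster 8, whose barcodes had medians of 3702 and 1415 UMIs over all libraries. Cluster 0, with a median of 1384 UMIs, held 4360 and 5225 barcodes of preclinical and onset blood and none of late blood. Whether neutrophils were nearly absent from the loaded late blood cells stays open. Of 2410 late blood barcodes with at least 4 of 8 NK cell markers, 10.3% (9.11 to 11.6%) held at least 10 UMIs of S100a8 and S100a9, with a median of 0. This share replaced one of 18.4% in 2 clusters that depended on the clustering, and was 38.0%, 11.2% and 6.21% at the preclinical, onset and peak stages (medians of 8, 0 and 0 UMIs). It does not measure how many neutrophils were loaded, since peak blood, with 42.2% neutrophils, had a lower share than late blood. The test therefore cannot decide the question. The UMI floor and depth of the library stay open, since thinning the earlier blood libraries to the late depth with its floor of 1399 UMIs left neutrophil shares of 27.0%, 6.24% and 3.91%, below their measured shares but above 0.289%. A lower yield and a biological fall of neutrophils cannot be told apart from these, because late blood was 1 library.

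Precursor cells stood apart in late spinal cord, where stem or progenitor cells were 6.0% of cells, basophils or mast cells 1.58% and erythroid cells 0.495%, each far from the other stages of that tissue. Blood left in the tissue is argued against, as the progenitor share of late spinal cord was 24.4 times that of late blood. Bone marrow taken with the spinal cord stays open as a candidate source: B cell precursor genes were 7.58-fold higher in late than in preclinical spinal cord (interval 5.21 to 11.4) and 1.81-fold higher than at peak (1.44 to 2.30), both references having been noted. The second fold was held down by Dntt (4.80 CPM at peak, 4.45 CPM late), while Vpreb1 went from 0.455 to 2.73 CPM, and the erythroid precursor genes were 1.92-fold higher than at the preclinical stage (1.66 to 2.22) and 1.16-fold higher than at onset (1.02 to 1.32), with most of their UMIs from Car2. In blood the B cell precursor genes went from 0.576 CPM at the preclinical stage to 7.45 CPM at the late stage, against 9.53 CPM in late spinal cord. Their rise was therefore not limited to spinal cord. Of the late blood level, Dntt made up 6.50 CPM, while Vpreb1 was at 0.745 CPM and Vpreb2 and Igll1 were not detected. Growth of precursors near the cord was not tested.

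Fkbp5 was higher at peak than at the preclinical stage in each of 12 tissue and class pairs and lower at the late stage than at peak in each of 13. A stress response to tissue handling is argued against for the rise to peak in most pairs, as the median of the stress genes was lower at peak in 11 of the 12. That fall was small in blood B cells (-0.119, percentile 59.4), and the median rose in spinal cord monocytes and macrophages (0.261, percentile 98.1). For the fall of Fkbp5 from peak to late the stress genes do not decide. Their median fell too in blood conventional dendritic cells (-0.329, percentile 0.52). In spinal cord it fell in T cells (-0.286, percentile 0.875), neutrophils (-0.991, percentile 0.05), monocytes and macrophages (-0.279, percentile 3.1) and NK cells (-0.018, percentile 33.2). In all other of the 13 pairs it rose. Pairs of the same tissue share their libraries, so they are not separate evidence. Free RNA is argued against, as B cells of peak blood had 45.5% of the highest class's Fkbp5 level, while of 7 other genes the highest share was 0.206%. A glucocorticoid response may underlie the pattern, since 7 other genes known to be induced by glucocorticoids lay under percentile 5 in 9 of 13 pairs from peak to late and over percentile 95 in 7 of 12 from preclinical to peak, but were low at peak in blood B cells (median log2 ratio -1.23, percentile 0.3) and spinal cord migratory dendritic cells (-0.856, percentile 3.15). Whether hormone, treatment or the day of collection differed between libraries was not tested.

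Late blood lay far from the other blood stages in its shares of basophils or mast cells (0.752%), conventional dendritic cells (7.81%), plasmacytoid dendritic cells (4.24%) and oligodendrocytes (0.0145%, 1 cell). Among named genes, 1 stage lay far from the others for Areg in spinal cord T cells (120.3 CPM at peak), Csf2 in blood T cells (1.53 CPM at onset, 1 UMI against 0 elsewhere), Klrb1c in blood T cells (227 CPM at the late stage), Cd300e in blood monocytes (122 CPM at the preclinical stage) and Ace in spinal cord monocytes and macrophages (21.9 CPM at the late stage). The same held in conventional dendritic cells for Nr4a3 in blood (1.34 CPM at peak, 1 UMI), Ptgs2 in blood (1.54 CPM at the late stage, 2 UMIs) and Wee1 in spinal cord (14.1 CPM at the late stage), and the values that rest on 1 or 2 UMIs show no difference beyond counting error. Migratory dendritic cells had a late minus preclinical share difference of 0.189 points in blood and -3.77 points in spinal cord, a difference between tissues that was not tested and that rests in spinal cord partly on cluster 33 (2.42% at the preclinical stage only), without which onset (2.25%) and peak (1.53%) lay above the preclinical stage (1.47%). Outside the named classes, cluster 18, led by Prg4, Alox15 and Retnla, held 9.31% of late blood cells, and cluster 11, a group of low RNA content led by immunoglobulin and C1q genes, held 18.6% of peak spinal cord cells.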

How the results depend on the processing

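The settings with at least 1400 UMIs, with neutrophils left out of the denominator and with clusters 10, 15 or 1 alone were chosen after seeing the data. Of 190 alternatives for the 20 main results 136 stayed close and 54 moved. Of 736 for genes named between tissues, 712 kept their call and 24 lost it, all of them neutrophil genes with a library left out. Of 1127 for genes named by stage, 1087 stayed close, 38 moved and 2 reversed, and of 403 for other shares, 338, 63 and 2 did. DESeq2 (1004, 923, 873, 3404 and 1223 genes for T cells, NK cells, neutrophils, monocytes and macrophages, and conventional dendritic cells) stayed within 1.5 times of edgeR. Except where stated, the cause of a change was not tested.

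The T cell count of 770 became 494 in cluster 10 alone, 383 in cluster 15 alone and 1156 with no filter on low counts. The neutrophil count of 703 became 1438 at 5% mitochondrial UMIs and 1577 and 1414 at resolutions 0.5 and 2, settings that left 19, 19 and 18 late blood neutrophils, so that this library did not enter. It became 357 with at least 1400 UMIs and 1267 with no filter. With stage as the replicate block the T cell count was 1174 and the neutrophil count 2230. Stage crosses tissue, and libraries of 1 stage are not known to share animals. The block also brought past the camera threshold the nitric oxide and late neutrophil lists in T cells, the hypoxia list in neutrophils, the scavenging list in monocytes and macrophages and the cytotoxicity list in conventional dendritic cells (adjusted p = 0.0123, 0.000843, 0.0476, 0.0341 and 0.0292). With an estimated correlation and no block none of these passed (adjusted p = 0.350, 0.242, 0.544, 0.306 and 0.322).

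With 1 library left out, counts ran from 465 (without peak spinal cord) to 1256 (late spinal cord) in T cells, where they were also 495 (onset blood), 487 (peak blood) and 500 (preclinical spinal cord). They ran from 497 (onset spinal cord) to 1115 (late blood) in NK cells, with 537 (peak blood) and 528 (preclinical spinal cord). In neutrophils they ran from 19 (preclinical blood) to 2589 (late spinal cord), with 20, 130 and 1440 (onset, peak and late blood) and 240, 349 and 450 (preclinical, onset and peak spinal cord). In monocytes and macrophages they ran from 1611 (preclinical spinal cord) to 4224 (late spinal cord), with 1700 (peak blood) and 1616 (onset spinal cord), and in conventional dendritic cells from 669 (preclinical spinal cord) to 2462 (late spinal cord), with 673 (late blood) and 684 (onset spinal cord). Camera with an estimated correlation called 6, 3, 0, 0 and 5 lists in T cells, NK cells, neutrophils, monocytes and macrophages, and conventional dendritic cells, against 14, 8, 15, 19 and 17.

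The late minus preclinical difference of blood B cells was 5.84 points with at most 5% mitochondrial UMIs, 14.7 with called doublets kept, 24.2 among named immune cells and 18.6 as a share of cells other than neutrophils. That of blood neutrophils was -63.0 with at least 1000 UMIs, -70.7 with at most 5% mitochondrial UMIs, -70.5 with at least 300 UMIs, clustered again, and -61.1 with at least 1400 UMIs. That of spinal cord T cells was 18.1 with at least 1000 UMIs, 19.9 among named immune cells, 19.4 with at least 1400 UMIs and 25.9 as a share of cells other than neutrophils. That of spinal cord monocytes and macrophages was -25.0 at Leiden resolution 0.5, -30.5 with at least 1400 UMIs and -47.1 as a share of cells other than neutrophils. It reversed for blood T cells to -2.40 in that last share, and for spinal cord neutrophils to 0.39 among named immune cells. Kcnk12 in spinal cord plasmacytoid dendritic cells (late over peak, 1 UMI at peak) reversed to -0.70 and -0.75 at Leiden resolution 0.5 and 2. Denominators without microglia, erythroid cells or neutrophils gave no value for those classes. With called doublets kept, the clusters rich in doublets entered the denominator of each share but no class. Among them, clusters 23, 24 and 30 scored highest for B cells. They held 531, 515 and 157 late blood barcodes, against 4, 1 and 12 at the preclinical stage. The 14.7 points of blood B cells therefore do not count barcodes of these clusters as B cells.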

Other observations

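The bounds for the splits of the libraries in this part were written after the results were seen. Other spinal cord classes also changed with stage. In NK cells, the granzyme gene Gzmc was not detected at the preclinical stage, was at 210 CPM at peak and was again not detected at the late stage, with log2 ratios of at least 4.85 and at most -4.94 against a floor of 3 counts, and Il7r, the receptor for interleukin-7, was at 19.4, 105 and 16.0 CPM. In plasmacytoid dendritic cells, Gbp2, an interferon-induced GTPase, was at 487 CPM at onset and 10.9 CPM at peak, and Cxcl10 went from 359 CPM to no detected UMI. In B cells, the scramblase gene Plscr1 was at 169 CPM at peak and 20.1 CPM at the late stage.

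Further gene groups differed between the tissues in the edgeR test. In T cells, 6 of 14 glycolysis genes rose in spinal cord (12 adjusted over the list alone, camera adjusted p = 1.95e-07, adjusted p = 0.216 with an estimated correlation), with Hk2, a hexokinase, at a log2 fold change of 3.15. Chemokine genes rose in 5 of 9 cases in neutrophils (6 adjusted over the list alone, camera adjusted p = 0.00198, adjusted p = 0.360 with an estimated correlation), with Cxcl3 at 6.28 but overlapping libraries. In monocytes and macrophages 8 of 10 proliferation genes rose (9 adjusted over the list alone, camera adjusted p = 0.000115, adjusted p = 0.293 with an estimated correlation), with Birc5, an inhibitor of apoptosis that acts in mitosis, at 3.50, though its level was 14.29 times higher in another class of the same library. Dissociation and stress genes rose in 13 of 16 cases in the same class (16 adjusted over the list alone, adjusted p = 0.152 with an estimated correlation) and in 13 of 16 in conventional dendritic cells (14 adjusted over the list alone, adjusted p = 0.0445 with an estimated correlation), where Egr1, an immediate early gene, was at 3.75.

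Each of the 35 ways to split the 8 libraries into groups of 4 was fitted for each class. The real split called 770 genes in T cells, 857 in NK cells, 2769 in monocytes and macrophages and 1386 in conventional dendritic cells. It was in each class the only 1 of 35 with that many. Splits that mix the tissues put a tissue difference into the spread within groups, so few calls were likely there. These counts therefore do not exclude chance. The highest other split called 7, 0, 0 and 884 genes in the same order, and the 884 came from preclinical blood with the preclinical, onset and peak spinal cord libraries against the rest. In neutrophils 2 of 35 splits called at least the 703 genes of the real one, the other calling 1084, with the 3 earlier blood libraries and late spinal cord against the rest. Chance was not excluded for the neutrophil count either, and that other split points to a structure of the samples other than tissue.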
